A study of Homo sapiens with 14 samples.

How the data were processed

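RNA was sequenced from 14 samples of established human acute myeloid leukaemia lines, prepared per the labels with a stranded mRNA kit after lentiviral transduction and flow sorting. MOLM14 gave 10 libraries in 5 groups of 2, one with an empty vector and 4 with an sWT1 construct, and MOLM13 and OCI-AML3 with a doxycycline-inducible vector gave 4 libraries, one with and one without doxycycline per line. The group of each sample was taken from its title and labels. The genotype label of the doxycycline samples names a doxycycline-inducible WT1, while their titles and the study's design name HOXA3, and the level of HOXA3 in those libraries is given with the results. The submitters' processing notes name Trimmomatic 0.39, FastQC without a version, STAR 2.5.3a and kallisto 0.46.2 and the builds GRCh38 and GRCh37, with no role or order. Which tool and build made each table is not stated.

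For MOLM13 and OCI-AML3 the values used are raw counts per Ensembl gene as deposited, whole numbers that were not scaled, for 58233 gene IDs, of which 57392 had a symbol in GENCODE 29. For MOLM14 the values used are estimated counts as deposited, unscaled and not all whole, summed by the authors to 39293 gene IDs, of which 33353 had a symbol, and given also per transcript. Expression as TPM was deposited for the same genes and transcripts, scaled by the authors for length and to a common sum. The deposited lengths are average effective transcript lengths in bases per gene and sample, per the file headers and values. The transcript lengths were not used. Coordinates and transcript structures were taken from GENCODE 29 on GRCh38.

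Totals were 23443188 and 27907424 counts in the empty vector libraries, 28517670 and 28527812 in sWT1--, 27302351 and 27791688 in sWT1-+, 26276680 and 24369766 in sWT1+-, and 22895130 and 24891566 in sWT1++. Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and a quasi-likelihood model was fitted in edgeR 4.0.16 with R 4.3.3. Each test was two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 10 MOLM14 libraries were fitted together, which left 15044 genes, 5 residual degrees of freedom and 3.1 prior degrees of freedom. From that model came each construct against the empty vector, the mean of the constructs against it, the plus against the minus in the first and in the second sign, the interaction of the signs, and WT1 and HOXA3 between pairs of constructs. The doxycycline comparison used the 4 libraries of both lines with the line as a block, 17268 genes, 1 residual degree of freedom and 17.8 prior degrees of freedom. CPM used TMM-scaled totals, and log2 levels a prior count of 2.

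WT1 and HOXA3 were named in every comparison. In the comparisons of sWT1 constructs, the 8 largest increases and the 8 largest decreases were named among genes past the threshold with a symbol, a mean of at least 1 CPM and no overlap between groups. In the doxycycline comparison, the 10 largest changes in each direction were named among genes with a symbol, a mean of at least 1 CPM and a log2 fold change of at least 1 in the same direction in both lines, whatever their adjusted p. In each list, up to 4 measured members with the smallest adjusted p could be named. The comparisons, the tests, this rule, the lists and the alternatives below were set before the data were examined.

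The 26 gene lists were the HOXA cluster, the HOXB cluster with HOX cofactors, a leukaemia stemness score, haematopoietic progenitor genes, markers of monocytes, granulocytes, erythroid and megakaryocyte cells, lymphoid cells, and stromal and epithelial cells, mitotic genes, DNA replication genes, ribosome biogenesis and MYC targets, the BCL2 family, drug transport and nucleoside analogue metabolism, p53 targets, DNA repair, interferon response, NF-kB and inflammatory genes, immediate early genes, MHC class II genes, described WT1 targets, unfolded protein and ATF4 response, hypoxia and glycolysis, cholesterol synthesis, mitochondrially encoded genes, and adhesion, homing and niche genes. Lists were tested by camera with a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and by fry from limma 3.58.1. No camera call of a list named in the results held with an estimated correlation. Some genes belong to more than one list, and the myeloid lists hold genes that these leukaemia lines express. Genes of the HOXA3-responsive lists had a log2 fold change of at least 1 in the same direction in both lines and a mean of at least 1 CPM, with at most 200 per list.

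Shares of KTS-plus WT1 counts were computed from the estimated transcript counts with 95% exact (Clopper-Pearson) intervals. Covariance expected from shared controls was taken from 100 simulated draws, in which the controls were redrawn too, with the spread pooled over the groups. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, a transcript length offset, limma with a trend on log2(TPM + 1), no filter on low counts, a fit of the libraries compared alone, the replicate number as a block, a log2 fold change of at least 1, and leaving out each MOLM14 library. For the doxycycline comparison they also held a fit without the line as a block and each line alone, where no library could be left out without losing the spread. For HOXA3-responsive lists they were a smaller fold and a mean of at least 5 CPM, and for covariances a different empty vector library for each construct. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

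The steps were tested on simulated data, drawn from the means and totals of the libraries with 200 genes set to change. For sWT1-- against the empty vector, over 14811 genes, 7 of 99 genes set to a log2 change of 1 were called (7.1%) and 62 of 99 set to 2 (62.6%), with 5 false calls. For the doxycycline comparison, over 16921 genes, 37 of 96 set to 1 were called (38.5%) and 79 of 98 set to 2 (80.6%), with 5 false calls.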

Results

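RNA sequencing was performed on 14 samples from human acute myeloid leukaemia cell lines. MOLM14, a monocytic line that carries a KMT2A fusion and an internal tandem duplication of FLT3, was transduced with an empty lentiviral vector or with one of 4 constructs that express a WT1 transcript, named sWT1--, sWT1-+, sWT1+- and sWT1++ in the labels. Each of these 5 groups had 2 libraries. MOLM13, a sister line of MOLM14, and OCI-AML3, a line with mutant NPM1, were transduced with a doxycycline-inducible HOXA3 vector and sequenced once with and once without the drug, so these 4 libraries had no replicate within a line. Transduced cells were sorted by flow cytometry and grown in serum-containing medium. WT1 encodes a zinc finger transcription factor that is often overexpressed in acute myeloid leukaemia, and HOXA3 is a homeobox gene of the HOXA cluster. The title of the series concerns isoform-specific WT1, HOXA3 and resistance to chemotherapy. The labels do not say what the signs of the constructs stand for. Titles of the empty vector libraries carry a letter K that those of the construct libraries lack, and the labels do not explain it.

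The MOLM14 libraries held between 22895130 and 28527812 gene-assigned counts. Totals in the HOXA3 lines were 67760392 without and 51337253 with doxycycline in MOLM13, and 42605642 without and 52769472 with it in OCI-AML3. Over the 15044 genes tested in MOLM14, the biological coefficient of variation was 0.286. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples. In a principal component analysis of the MOLM14 libraries, component 1 held 38.5% of the variance. The sWT1-- libraries lay at -50 and -97.9 on it, the empty vector libraries at -8.7 and -4.9, and sWT1++ replicate 1 at -15.1. The other 5 libraries lay between 6.3 and 55.6, and the sWT1++ replicates were thus on opposite sides of the empty vector.

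WT1 was far higher with every construct than with the empty vector. On GRCh38 (GENCODE 29), the gene (ENSG00000184937) lies on chromosome 11 from 32387775 to 32435630 on the reverse strand. Its level was 39.9 ± 2.84 CPM, the count scaled to the library total (SD, n = 2), with the empty vector, 493 ± 24.9 with sWT1--, 684 ± 114 with sWT1-+, 592 ± 11.1 with sWT1+- and 701 ± 77.7 with sWT1++. These levels were 12.3-fold, 17.1-fold, 14.8-fold and 17.6-fold above the empty vector, with log2 fold changes of 3.63 ± 0.18 (SE), 4.10 ± 0.19, 3.89 ± 0.19 and 4.13 ± 0.19. edgeR's adjusted p was 0.000565, 0.000253, 0.000355 and 0.000239 in the same order. Between constructs, WT1 differed by at most 0.51 on the log2 scale, in sWT1++ against sWT1--, and no pair passed the threshold. With a transcript length offset the difference of sWT1+- from sWT1-- turned from 0.27 to -0.34.

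HOXA3 (ENSG00000105997, chromosome 7 from 27106184 to 27152581 on the reverse strand) was highest with sWT1+-, at 10.6 ± 0.0946 CPM (SD, n = 2), against 7.29 ± 0.068 with the empty vector. It was 4.83 ± 1.23 with sWT1--, 5.18 ± 1.29 with sWT1-+ and 5.75 ± 1.06 with sWT1++, in each case below the empty vector. No comparison of HOXA3 with the empty vector passed the threshold. The log2 fold change was 0.54 ± 0.28 with sWT1+- (1.45-fold, adjusted p = 0.76), -0.59 ± 0.29 with sWT1-- (adjusted p = 0.472), -0.49 ± 0.29 with sWT1-+ (adjusted p = 0.617) and -0.34 ± 0.29 with sWT1++ (adjusted p = 0.946). With sWT1-+ it was 0.14 by limma on log2(TPM + 1). Without 1 library at a time it ranged from -0.88 to -0.36 in sWT1--, -0.77 to -0.26 in sWT1-+ and -0.54 to -0.19 in sWT1++. Between constructs, HOXA3 was 2.19-fold higher in sWT1+- than in sWT1-- (log2 1.13 ± 0.29, adjusted p = 0.13) and 2.04-fold higher than in sWT1-+ (log2 1.03 ± 0.29, adjusted p = 0.55). It was lower in sWT1++ than in sWT1+- by a log2 fold change of -0.88 ± 0.29 (adjusted p = 0.783). DESeq2 called the difference between sWT1+- and sWT1-- (adjusted p = 0.0113), and the tests across pairs rest on 2 libraries per group. HOXA3 overlaps HOXA4, HOXA5, HOXA6 and antisense genes and WT1 overlaps an antisense gene in the annotation, and whether strand was used in the counting is not stated.

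**Figure D1:**
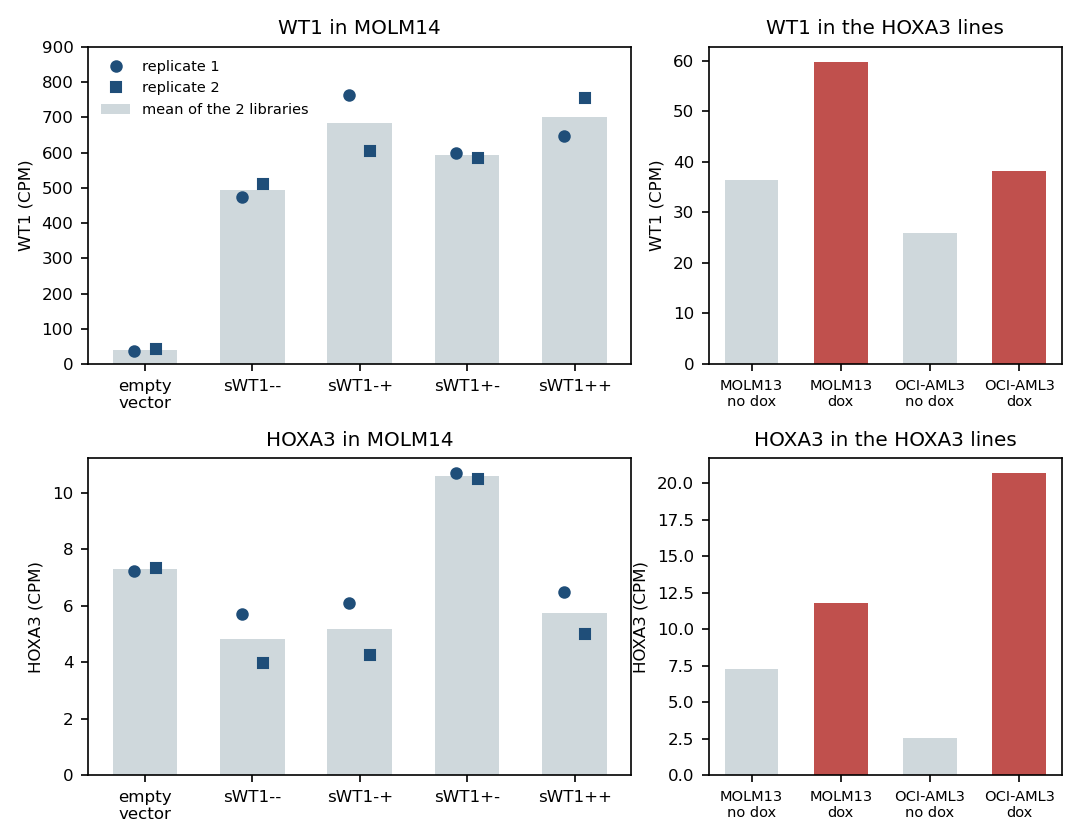
Levels of WT1 (top) and HOXA3 (bottom) in CPM in the MOLM14 groups (left, bars are means and points the 2 replicates) and in the HOXA3 lines with and without doxycycline (right, 1 library per bar). WT1 was 39.9 CPM with the empty vector and at least 493 with each construct, and HOXA3 in OCI-AML3 was 2.56 CPM without and 20.7 with doxycycline.

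The forms of WT1 counted in the transcript tables differed between constructs. Alternative use of a splice site adds 9 bases to an exon of WT1 that encode lysine, threonine and serine (KTS) between the third and the fourth zinc finger. This exon runs on chromosome 11 from 32391972 to 32392064 in the KTS-plus form and from 32391981 to 32392064 in the KTS-minus form, and a 51-base exon lies from 32416490 to 32416540. Of the WT1 counts in transcripts with either form, the KTS-plus share was 49.5% (95% exact Clopper-Pearson interval 46% to 53%) and 46.4% (43.4% to 49.4%) in the empty vector libraries. It was 83.4% and 82.3% in sWT1-+, 90.2% and 81.3% in sWT1++, and 14.2% and 5.7% in sWT1+-. The 2 sWT1-- libraries stood apart from each other, at 26.9% (26.1% to 27.6%) in replicate 1 and 82.1% (81.4% to 82.8%) in replicate 2. By the 2 short full-length transcripts alone the shares in sWT1-- were 13.6% and 74.9%. Over all transcripts with either form, the shares by TPM, which gives more weight to a short partial KTS-plus transcript, were 47.3% and 45.3% with the empty vector, 57.3% and 93.6% in sWT1--, 92.7% and 92.5% in sWT1-+, 44.7% and 17.9% in sWT1+-, and 96.1% and 92.8% in sWT1++. By TPM, sWT1+- replicate 1 was thus near the empty vector libraries. By the 2 short full-length transcripts alone it was at 3.2%, against 53.3% and 53.4% with the empty vector. These shares are estimates by transcript assignment and their intervals cover counting error only. The annotation holds no short transcript that lacks the 51-base exon and the KTS bases together, or that has both in full, so reads of such forms had to be assigned to other transcripts.

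**Figure D2:**
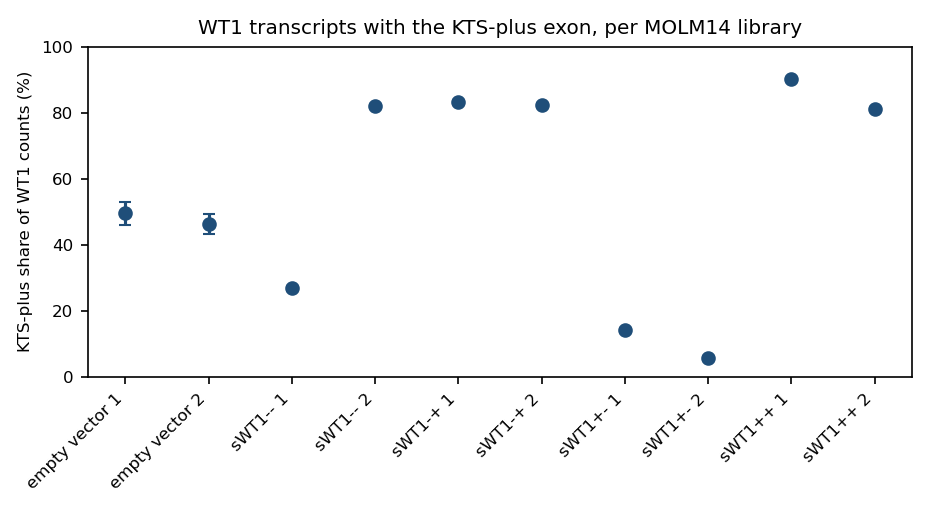
Share (%) of WT1 counts in transcripts with the KTS-plus exon in each MOLM14 library, with 95% exact (Clopper-Pearson) intervals. The sWT1+- libraries lie at 14.2% and 5.7%, the sWT1-- libraries at 26.9% and 82.1%, and the sWT1-+ and sWT1++ libraries at 81.3% or more.

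In sWT1--, antiviral genes of the interferon response were higher than with the empty vector. edgeR called 7 genes of 15044, all up. Besides WT1 these were USP18, a protease that removes ISG15 and restrains interferon signalling (6.12-fold, log2 2.61 ± 0.18 SE, adjusted p = 0.00364), and HERC5, the ligase that attaches ISG15 (log2 2.04 ± 0.18, adjusted p = 0.0149). The others were PARP14 (log2 1.83 ± 0.17, adjusted p = 0.0194), EIF2AK2, the kinase PKR that senses double-stranded RNA (log2 1.74 ± 0.18, adjusted p = 0.0288), SAMD9 (log2 1.52 ± 0.17, adjusted p = 0.0439) and DTX3L (log2 1.43 ± 0.16, adjusted p = 0.039). Each of these 6 genes is known to be induced by interferon. Of the 28 measured members of the interferon response list, 28 rose when adjusted over the list alone and 1, USP18, when adjusted over all genes. DESeq2 called 26 of the 28. The median log2 fold change of the list was 3.93 (camera adjusted p = 2.46e-57). With an estimated correlation the call was lost (adjusted p = 0.261 with an estimated correlation). MX1, an antiviral GTPase of the list, stood at 71.7 and 54.6 CPM in the sWT1-- libraries and at 3.24 and 2.21 CPM in the empty vector libraries.

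Cholesterol synthesis genes also rose in sWT1--, with 11 of 17 measured members up when adjusted over the list alone. The edgeR count over all genes was 0, with 12 members at an unadjusted p under 0.05, 7 called by DESeq2 and 0 by limma-voom. The median was 0.88 (camera adjusted p = 3.21e-16; adjusted p = 0.361 with an estimated correlation). SQLE, the squalene epoxidase, was 5.13-fold higher (log2 2.36 ± 0.44, adjusted p = 0.241) and HMGCS1, which makes HMG-CoA, had a log2 fold change of 1.49 ± 0.27. Of the 13 mitochondrially encoded genes, 12 fell when adjusted over the list alone. The edgeR count over all genes was 0, against 12 at an unadjusted p under 0.05, 11 by DESeq2 and 0 by limma-voom. Their median was -1.32 (camera adjusted p = 3.25e-18; adjusted p = 0.361 with an estimated correlation), or -0.80 without empty vector replicate 1. These genes held 9.19% and 5.41% of the counts in the empty vector libraries and 3.46% and 2.91% in the sWT1-- libraries. Among described WT1 targets, 3 of 19 fell when adjusted over the list alone. The edgeR count over all genes was 0, with 7 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. The 3 genes were TERT, the catalytic subunit of telomerase (log2 -3.51 ± 0.51, adjusted p = 0.121), PODXL, a sialomucin of the podocyte surface (log2 -3.13 ± 0.70), and BCL2, an inhibitor of apoptosis (log2 -1.12 ± 0.31, or -1.78 to -0.67 without 1 library at a time). TERT was at 11.9 and 12.5 CPM with the empty vector and at 1.28 and 0.849 CPM with sWT1--. The list as a whole had a median of -0.13 (camera adjusted p = 0.00936; adjusted p = 0.555 with an estimated correlation), which turned to 0.04 without sWT1-- replicate 1 and was 0.00 without empty vector replicate 1.

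Markers of monocytes and MHC class II genes moved with the interferon genes in this group and differed between its replicates. Relative to the empty vector mean, the mean log2 level of the monocyte markers was 0.64 in replicate 1 and 2.08 in replicate 2, and that of the MHC class II genes was 1.13 and 2.53. The interferon genes stood at 3.59 and 3.92 in the same libraries. The monocyte list had a median fold change of 1.17 on the log2 scale, which was 0.40 without replicate 2 (adjusted p = 0.107), and with both replicates it was higher by camera (adjusted p = 0.616 with an estimated correlation). Of its 21 members, 4 had an unadjusted p under 0.05, and edgeR called 0, DESeq2 1 and limma-voom 0. Of the 9 MHC class II genes, 3 had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom called 0. The median log2 fold change of these 9 ranged from 0.83 to 2.67 without 1 library at a time. The count of called genes moved with the libraries in the fit, those outside the comparison included: it was 0 without empty vector replicate 1, where WT1 itself had an adjusted p of 0.05, and 1 without replicate 2. It was 4 without sWT1-- replicate 2, 2 without either sWT1+- replicate, 3 without either sWT1++ replicate and 18 without either sWT1-+ replicate, while DESeq2 called 330 genes.

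In sWT1-+, cholesterol synthesis genes were higher and edgeR called 1 gene, WT1. Of the 17 members, 10 rose when adjusted over the list alone. The edgeR count of members over all genes was 0, with 10 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. The median was 0.84 (camera adjusted p = 2.91e-13; adjusted p = 0.709 with an estimated correlation), or 0.52 without sWT1-+ replicate 2. SQLE was 5.86-fold higher (log2 2.55 ± 0.44, or 1.74 to 3.06 without 1 library at a time). CD34, a surface marker of haematopoietic progenitors, was low in MOLM14 and lower still in this group, at 0.0708 and 0.206 CPM against 1.46 and 0.885, and fell when adjusted over the progenitor list alone (adjusted p = 0.0141) but not over all genes (adjusted p = 0.27). Immediate early genes had a median of -0.70 (camera adjusted p = 5.81e-05; adjusted p = 0.709 with an estimated correlation), a call that ended without sWT1-+ replicate 1 (adjusted p = 0.0578). Of the 22 members, 6 had an unadjusted p under 0.05, and edgeR called 0, DESeq2 1 and limma-voom 0. The edgeR count for this construct was 89 without sWT1-+ replicate 1, and DESeq2 called 181 genes.

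In sWT1+-, cholesterol synthesis genes were higher and granulocyte markers had a negative median. WT1 was the only gene called by edgeR. Of the cholesterol genes, 12 of 17 rose when adjusted over the list alone, with a median of 0.87 (camera adjusted p = 4.07e-26; adjusted p = 0.448 with an estimated correlation). The edgeR count over all genes was 0, with 12 members at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma-voom. SQLE was 5.26-fold higher than with the empty vector (adjusted p = 0.76). Among 16 granulocyte markers, MS4A3, a gene of granulocyte and monocyte progenitors (log2 -2.03 ± 0.50), RNASE3, which encodes the eosinophil cationic protein (log2 -1.14 ± 0.30), and CAMP, the cathelicidin gene, fell when adjusted over the list alone. The edgeR count over all genes was 0, with 5 markers at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. Their median was -0.80 (camera adjusted p = 2.51e-07; adjusted p = 0.505 with an estimated correlation). MEIS2, a homeobox cofactor of HOX proteins, rose when adjusted over its list alone and not over all genes (log2 0.78 ± 0.22, adjusted p = 0.76). The 21 mitotic genes had a median of 0.51, which camera called (adjusted p = 0.66 with an estimated correlation), or 0.32 without empty vector replicate 1. Of these genes 0 had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom called 0. DESeq2 called 38 genes in this group.

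In sWT1++, cholesterol synthesis genes were higher. WT1 was the gene called by edgeR, against 15 genes by DESeq2. Of the 17 cholesterol genes, 7 rose when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 3.18e-17; adjusted p = 0.586 with an estimated correlation), which was 1.02 without replicate 1 and 0.32 without replicate 2. The edgeR count of members over all genes was 0, with 9 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom. SQLE was 4.96-fold higher (log2 2.31 ± 0.44, adjusted p = 0.946). The log2 fold change was 0.78 ± 0.20 for FDFT1, the squalene synthase, and 1.01 ± 0.27 for HMGCS1 (adjusted p = 0.946 for both). Without 1 library at a time they ranged from 0.47 to 1.02 and from 0.55 to 1.34. The mitochondrially encoded genes had a median of -0.71 (camera adjusted p = 2.77e-06; adjusted p = 0.586 with an estimated correlation), which was -0.22 without empty vector replicate 1 (adjusted p = 0.366) and -1.11 without replicate 2. Of the 13 genes, 4 had an unadjusted p under 0.05, and edgeR, DESeq2 and limma-voom called 0. The replicates of this group stood apart in inflammatory genes, whose mean log2 level was 0.19 in replicate 1 and -2.08 in replicate 2. Their list median of -0.47 turned to 0.11 without replicate 2, so no direction of that list is given for the group.

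**Figure D3:**
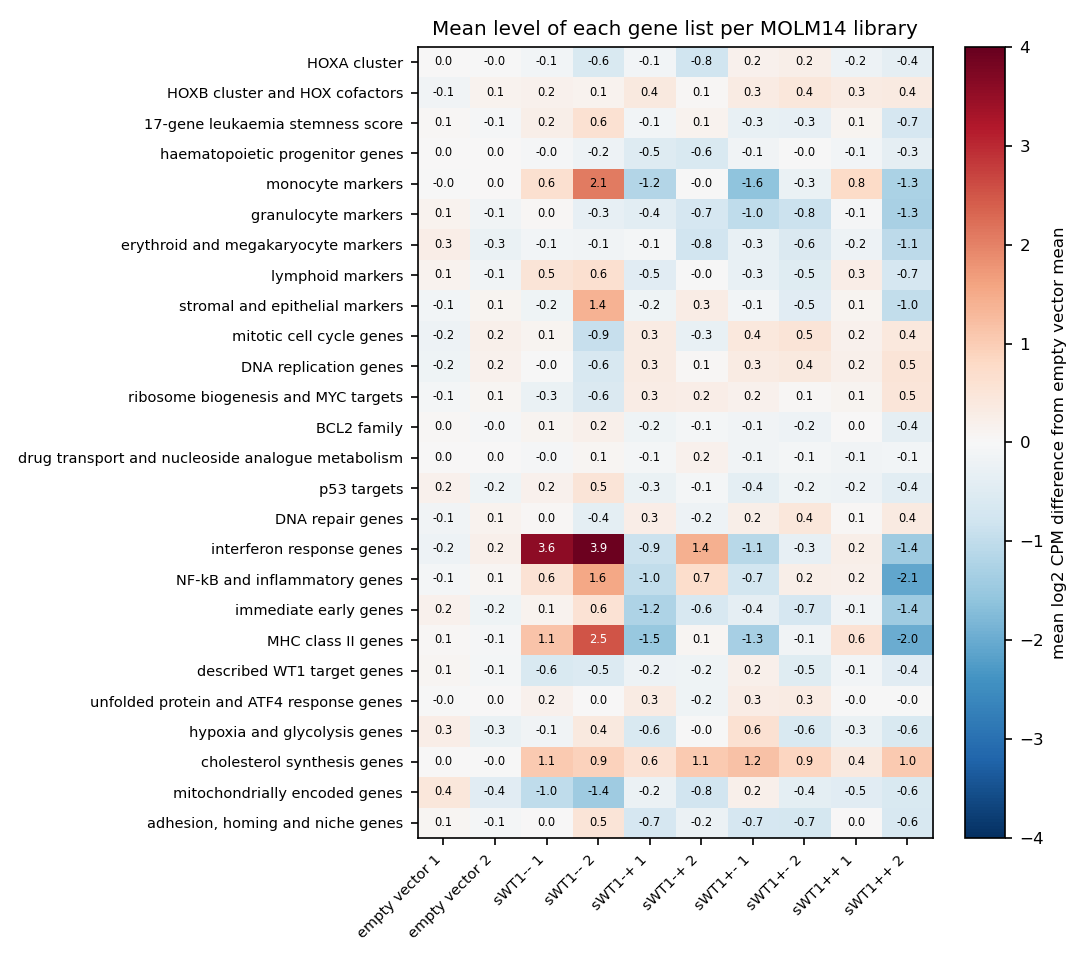
Mean log2 CPM of each of the 26 gene lists in each MOLM14 library, as the difference from the mean of the 2 empty vector libraries (colour scale and printed values). Interferon response genes stand at 3.59 and 3.92 in the sWT1-- libraries and between -1.41 and 1.42 in the other 8, and cholesterol synthesis genes stand between 0.40 and 1.17 in the 8 sWT1 libraries.

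Taking the mean of the constructs, WT1 was 15.3-fold above the empty vector (log2 3.94 ± 0.17 SE, adjusted p = 0.000185) and was the gene called by edgeR. HOXA3 had a log2 fold change of -0.22 ± 0.22 (adjusted p = 1), and of 0.11 by limma on log2(TPM + 1). Cholesterol synthesis genes had the smallest camera p of the 26 lists, with 13 of 17 up when adjusted over the list alone and a median of 0.73 (camera adjusted p = 1.93e-34; adjusted p = 0.263 with an estimated correlation). The edgeR count over all genes was 0, with 13 members at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma-voom. The comparisons of the 4 constructs share the 2 empty vector libraries, so a rise in each is not a repeat of it in separate data. A difference common to the constructs also cannot be told apart from whatever the unexplained K in the empty vector titles marks. SQLE was 5.29-fold higher (adjusted p = 0.6). SQLE was between 20.8 and 52 CPM in the 8 sWT1 libraries, against 5.22 and 7.19 CPM with the empty vector. MS4A3 was at 233 and 139 CPM with the empty vector and between 33.4 and 110 CPM in the 8 sWT1 libraries (log2 -1.63 ± 0.34), a fall when adjusted over the granulocyte list alone (adjusted p = 0.0225) and not over all genes (adjusted p = 1). The 16 granulocyte markers had a median of -0.42 (camera adjusted p = 2.55e-07; adjusted p = 0.441 with an estimated correlation), or -0.19 without empty vector replicate 1, with 2 at an unadjusted p under 0.05, 0 called by edgeR, 1 by DESeq2 and 0 by limma-voom. DESeq2 called 26 genes for this mean.

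The 4 constructs form a square of signs, so each sign was compared across the other. With a plus as the first sign, interferon genes were lower than with a minus, and HERC5 was the single gene called (log2 -1.58 ± 0.13 SE, adjusted p = 0.0212). All 28 interferon genes fell when adjusted over the list alone, with a median of -2.78 (camera adjusted p = 5.7e-55; adjusted p = 0.299 with an estimated correlation). The edgeR count of members over all genes was 0, with 28 at an unadjusted p under 0.05, 25 by DESeq2 and 0 by limma-voom. The low value of this contrast came with the high level of the sWT1-- libraries, since those of sWT1-+ stood at -0.86 and 1.42. Mitotic genes had a median of 0.50 and DNA replication genes of 0.42, both higher by camera (adjusted p = 0.385 with an estimated correlation for both). The mitotic median was 0.82 without sWT1-- replicate 1 and 0.29 without replicate 2. At an unadjusted p under 0.05 were 5 mitotic and 12 DNA replication genes, while edgeR called 0, DESeq2 1 and 0, and limma-voom 0. MT-ND6, a subunit of complex I, rose when adjusted over the mitochondrial list alone and not over all genes (log2 1.3 ± 0.23, adjusted p = 0.304). HOXA3 had a log2 difference of 0.64 ± 0.20 (adjusted p = 0.42) and WT1 of 0.15 ± 0.12, which was 0.07 to 0.24 without 1 library at a time and -0.09 with a transcript length offset. HERC5 was no longer called when any library other than sWT1-+ replicate 1 was left out, with adjusted p between 0.05 and 0.242, and DESeq2 called 277 genes.

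With a plus as the second sign, the 28 interferon genes had a median of -1.26, of which 11 fell when adjusted over the list alone (camera adjusted p = 5.59e-24; adjusted p = 0.682 with an estimated correlation). That median was -2.21 without sWT1-+ replicate 2 and -1.96 without sWT1++ replicate 1. Of the 28, 18 had an unadjusted p under 0.05, and edgeR called 0, DESeq2 7 and limma-voom 0. Among genes of ribosome biogenesis, 3 of 20 rose when adjusted over the list alone, including NOP16 (log2 0.49) and RRP9 (log2 0.46), both of the nucleolus, and the list had a median of 0.37 (camera adjusted p = 1.29e-11; adjusted p = 0.682 with an estimated correlation), or 0.24 without sWT1++ replicate 2, with 12 members at an unadjusted p under 0.05, 0 called by edgeR, 3 by DESeq2 and 0 by limma-voom. HOXA3 had a log2 difference of -0.39 ± 0.20 (adjusted p = 0.417; -0.53 to -0.25 without 1 library at a time) and WT1 of 0.36 ± 0.12. edgeR called 0 genes, with 2080 at an unadjusted p under 0.05 against 752 expected by chance. DESeq2 called 361, limma-voom 0 and limma on log2(TPM + 1) 3.

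The interaction of the signs, which is the difference of the effect of the second sign between constructs with a plus and with a minus in the first, was widest in interferon, monocyte and MHC class II genes. Adjusted over the list alone, 19 of 28 interferon genes had a positive interaction (median log2 3.11), as did 10 of 21 monocyte markers (median 2.96), among them S100A8, KLF4 and CD163. Of the mitochondrially encoded genes, 4 of 13 had a negative one (median -1.28). All 3 lists passed camera's preset test and none passed otherwise (adjusted p = 0.651 with an estimated correlation for each). Over all genes, 20 interferon, 13 monocyte and 8 mitochondrial members had an unadjusted p under 0.05, while edgeR and limma-voom called 0 and DESeq2 15, 8 and 4. HOXA3 had an interaction of -0.98 ± 0.40 (adjusted p = 0.243) and WT1 of -0.23 ± 0.23, which was -0.40 to -0.05 without 1 library at a time and 0.48 with a transcript length offset. Over all genes edgeR called 0, with 2903 at an unadjusted p under 0.05 against 752 expected, DESeq2 966, limma-voom 0 and limma on log2(TPM + 1) 2. The interferon median was 4.87 without sWT1-+ replicate 2, and without sWT1++ replicate 1 that of monocyte markers was 1.31 and that of MHC class II genes 0.97 (adjusted p = 0.0834). Without sWT1-- replicate 2 the monocyte median was 1.91. The monocyte and MHC class II levels behind it differed within groups, at 0.77 and -1.26 for monocyte markers and 0.59 and -1.98 for MHC class II genes in the sWT1++ replicates.

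The effects of the constructs overlapped unevenly across genes. Since they share the 2 empty vector libraries, unchanged groups were simulated in 100 draws, with controls redrawn too and the spread pooled over all groups. This gave a covariance of log2 fold changes between 0.12 and 0.13 and a correlation between 0.50 and 0.51. The empty vector libraries lay closer together (SD of the log2 difference 0.51) than the replicates of each construct (0.77 to 0.81). The simulated covariance can therefore be too high for these controls, and a value below it does not show that constructs share less. Observed covariances were 0.19 for sWT1-+ with sWT1+-, 0.17 for sWT1-+ with sWT1++ and 0.18 for sWT1+- with sWT1++, above the simulated value by 0.06, 0.04 and 0.05. Those of sWT1-- were 0.03 with sWT1-+, 0.01 with sWT1+- and 0.03 with sWT1++, below the simulated value. The correlations across genes, which are not independent replicates, were 0.44, 0.41 and 0.57 for the former pairs and 0.05, 0.02 and 0.07 for the latter. The mean covariance of the 6 pairs was 0.10, against a simulated 0.12 ± 0.003 (SD over draws), and 0.03 when each construct of a pair was set against a different empty vector library. With such split controls the pairs without sWT1-- kept covariances of 0.12, 0.10 and 0.11, while those with it had -0.04, -0.06 and -0.04. WT1, which each construct expresses, was the 1 gene called in both of any pair.

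With doxycycline, HOXA3 was higher and the median of monocyte markers was lower in both HOXA3 lines. HOXA3 rose from 2.56 to 20.7 CPM in OCI-AML3 and from 7.30 to 11.8 CPM in MOLM13, a fitted 3.54-fold increase (log2 1.83 ± 0.45 SE, adjusted p = 0.0346). In MOLM13 the increase was 1.61-fold, no more than that of WT1 in the same libraries (1.64-fold), and the genotype label of these samples names an inducible WT1 where their titles name HOXA3. Of 17268 genes, edgeR with the line as a block called 382, of which 23 rose and 359 fell, and all 382 moved the same way in both lines. That agreement is largely built into the test, in which a difference between the lines counts as spread. S100A9, a calcium-binding protein of myeloid cells, fell from 41.9 to 5.59 CPM in MOLM13 and from 700 to 12.1 CPM in OCI-AML3 (log2 -4.41 ± 0.47, adjusted p = 2.81e-05), and LSP1, an actin-binding protein of leukocytes, from 141 to 16.8 and from 15.1 to 0.357 CPM (log2 -3.97 ± 0.38). Among the genes that rose were INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum (log2 1.69 ± 0.26, adjusted p = 0.000953) and SCD, the stearoyl-CoA desaturase (log2 1.33 ± 0.21, adjusted p = 0.00109).

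By the fit over both lines, the other genes with the widest falls were PADI4, a peptidylarginine deiminase of granulocytes (log2 -5.13), KRT81 (-5.02), the secreted osteopontin gene SPP1 (-4.80), the stress cytokine GDF15 (-4.60), TGM3 (-4.07), S100A8, the partner of S100A9 (-3.98), COL22A1 (-3.90) and NUPR1 (-3.89). The lines differed in size, and in the same order the log2 fold changes were -3.33, -2.44, -4.14, -3.57, -3.06, -1.94, -2.19 and -4.52 in MOLM13 and -5.26, -5.97, -4.68, -4.83, -4.02, -5.83, -4.73 and -2.83 in OCI-AML3. The treated MOLM13 library held 91 counts of S100A8, 15 of NUPR1 and 9 or fewer of the other 6. Other rises were those of SLC6A13, a transporter of GABA (log2 4.30 ± 0.69), LOXL4 (2.68), ABCC13 (2.37) and SIPA1L2 (1.16), and ENSG00000229855, which has no assigned name here, had a log2 change of 1.89 (adjusted p = 0.0511). In MOLM13 the change was 1.69 for SLC6A13, from 2 to 9 counts, and 1.33 for LOXL4, against 4.64 and 3.70 in OCI-AML3. WT1 went from 36.4 to 59.7 CPM in MOLM13 and from 26 to 38.1 CPM in OCI-AML3 (log2 0.63 ± 0.23, adjusted p = 0.253). At a log2 change of at least 1 in both lines, 316 genes were lower and 8 higher, besides 31 that went in opposite directions. The fold changes of the lines correlated at 0.246 across genes, which are not independent replicates.

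The test had 1 residual degree of freedom, because each line gave 1 library per arm, and no doxycycline-treated line without the HOXA3 vector was sequenced. With median-ratio (RLE) size factors edgeR called 107 genes, 5 up and 102 down, all among the 382, and HOXA3 had an adjusted p of 0.207, while without the line as a block it called 0, with 198 at an unadjusted p under 0.05. DESeq2 called 376 and limma-voom 439, of which 333 and 374 were among the 382. S100A9, LSP1, INSIG1, SCD, SLC6A13, ABCC13, ITGAM, CSF1R, BCL2A1 and JUN kept their call with RLE factors, and HOXA3, S100A8, LOXL4, GATA2, CDA, MPO and EGR1 were among those that did not.

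**Figure D4:**
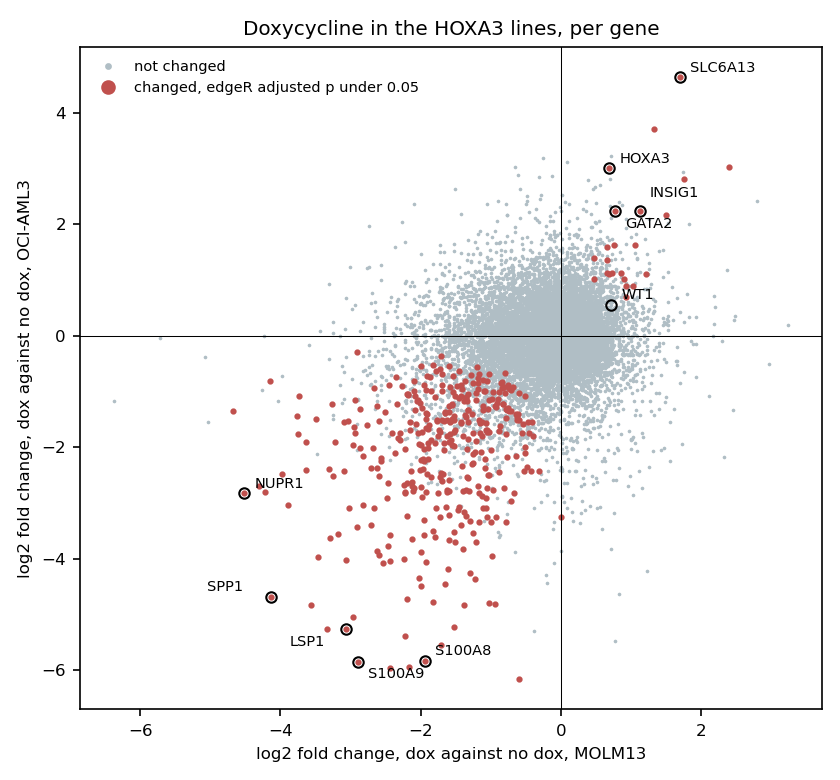
Log2 fold change with doxycycline of each tested gene in MOLM13 (x axis) and OCI-AML3 (y axis), with the 382 genes called by edgeR in red and some named genes circled. The called genes are mostly in the lower left part (359 fell), and HOXA3 lies at 0.69 in MOLM13 and 3.00 in OCI-AML3.

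Monocyte markers were mostly lower with doxycycline, and granulocyte markers moved both ways. Of 18 measured monocyte markers, 11 fell when adjusted over the list alone and 9 over all genes, with a median of -1.35 (-0.63 in MOLM13 and -2 in OCI-AML3; camera adjusted p = 1.26e-18; adjusted p = 0.538 with an estimated correlation). ITGAM, an integrin subunit of myeloid cells, fell by 1.75 ± 0.24 on the log2 scale and CSF1R, the receptor of macrophage colony-stimulating factor, by 1.39 ± 0.23. Of 15 granulocyte markers, 5 fell and 1 rose when adjusted over the list alone, and 4 fell over all genes. Among them were MMP9 (log2 -2.13 ± 0.47), CEBPE, a transcription factor of granulocyte maturation (log2 -1.20 ± 0.28), and MPO, the myeloperoxidase (log2 -0.93 ± 0.23). The median of that list was -0.15, at -0.32 in MOLM13 and 0.00 in OCI-AML3 (camera adjusted p = 0.0169; adjusted p = 0.547 with an estimated correlation). In the 9 measured progenitor genes, GATA2, a transcription factor of stem and progenitor cells, rose by both adjustments (log2 1.5 ± 0.30, adjusted p = 0.00809) and the median was -0.03, while camera's direction was up (adjusted p = 0.173). Of the 13 measured genes of the leukaemia stemness score, 1 rose and 3 fell when adjusted over the list alone, and AKR1C3, an aldo-keto reductase, fell over all genes (log2 -1.86 ± 0.35). The median was -0.45 (camera adjusted p = 0.071).

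Inflammatory, immediate early, antigen presentation and hypoxia genes were lower with doxycycline. Of 21 NF-kB and inflammatory genes, 5 fell by both adjustments. They included ICAM1 (log2 -2.28 ± 0.39), the cytokine IL1B (-2.20 ± 0.37), IER3 (-2.09) and the chemokine CXCL8 (-1.85 ± 0.38), and the median was -0.68. Of 21 immediate early genes, 10 fell when adjusted over the list alone and 3 over all genes, namely the transcription factors JUN (log2 -2.17 ± 0.32), EGR1 (-2.42 ± 0.41) and EGR2 (-2.33), with a median of -0.76. Of 9 MHC class II genes, 5 fell when adjusted over the list alone, among them HLA-DMA (log2 -1.5 ± 0.40) and CD74, the invariant chain (-0.71 ± 0.19). Over all genes edgeR called 0 of the 9, with 7 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 1 each. Their median was -1.41. Of 23 hypoxia and glycolysis genes, 12 fell when adjusted over the list alone and 5 over all genes. These included NDRG1 (log2 -1.59 ± 0.25), the glucose transporter gene SLC2A3 (-1.23) and ADM, the adrenomedullin gene (-2.30 ± 0.47), with a median of -0.62. Camera gave these lists an adjusted p of 4.63e-09, 8.03e-10, 2.14e-06 and 4.31e-14 in turn (adjusted p = 0.538 with an estimated correlation for each). In MOLM13 and OCI-AML3 the medians were -0.39 and -1 for inflammatory genes, -0.11 and -1.25 for immediate early genes, -1.32 and -1.06 for MHC class II genes, and -0.57 and -0.38 for hypoxia genes.

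Cholesterol synthesis genes rose, with 14 of 17 up when adjusted over the list alone and 8 over all genes. Besides INSIG1 these held FDFT1 (log2 0.99 ± 0.20) and LSS, the lanosterol synthase (log2 1.19 ± 0.26). Their median was 0.90, at 0.66 in MOLM13 and 1.02 in OCI-AML3 (camera adjusted p = 4.68e-26; adjusted p = 0.538 with an estimated correlation). Of the 13 mitochondrially encoded genes, 9 rose when adjusted over the list alone and MT-ATP6, a subunit of ATP synthase, over all genes (log2 0.74 ± 0.19), with a median of 0.46, at 0.20 in MOLM13 and 0.72 in OCI-AML3 (camera adjusted p = 1.69e-08; adjusted p = 0.538 with an estimated correlation). Of 14 measured genes of the HOXA cluster, HOXA3 itself was the one that rose by both adjustments, and the median was 0.35 (camera adjusted p = 0.00138; adjusted p = 0.547 with an estimated correlation).

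Genes tied to cell survival and drug handling changed in few members. In the BCL2 family, 2 of 15 fell by both adjustments, BCL2A1, an inhibitor of apoptosis (log2 -2.31 ± 0.31, adjusted p = 0.000307), and BMF, a promoter of it (log2 -0.95 ± 0.22), with a median of -0.16 (camera adjusted p = 0.106). Of 17 genes of drug transport and nucleoside analogue metabolism, 2 fell when adjusted over the list alone and 1 over all genes, CDA, the cytidine deaminase that inactivates cytarabine (log2 -1.49 ± 0.32, adjusted p = 0.0158). CDA went from 7.25 to 1.39 CPM in MOLM13 and from 59.4 to 35.5 CPM in OCI-AML3, and limma-voom gave it an adjusted p of 0.0539. The median was 0.15 (camera adjusted p = 0.612). Of 20 p53 targets, 3 fell when adjusted over the list alone and 2 over all genes, GDF15 and BTG2, with a median of -0.04 (camera adjusted p = 0.0618). Of 20 genes of the unfolded protein and ATF4 responses, 4 fell and 1 rose when adjusted over the list alone, and DDIT4 (log2 -1.78 ± 0.33) and the cystine transporter gene SLC7A11 (log2 -1.01) fell over all genes. The median was -0.05 (camera adjusted p = 0.256). Of 18 adhesion and homing genes, 6 fell when adjusted over the list alone and 4 over all genes, CD52, ICAM3 (log2 -2.37 ± 0.50), ITGB7 (log2 -1.73 ± 0.38) and CD9 (log2 -1.44). Their median was -0.31 (camera adjusted p = 0.000299; adjusted p = 0.538 with an estimated correlation), and 0.04 in OCI-AML3 alone. Of 19 described WT1 targets, 8 fell when adjusted over the list alone and 2 over all genes, EGR1 and ETS1 (log2 -1.06), with a median of -0.55, at 0.00 in MOLM13 and -0.41 in OCI-AML3 (camera adjusted p = 0.0013; adjusted p = 0.538 with an estimated correlation).

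Few markers of other cell types were measured, and lists of proliferation had small medians. Of 6 measured stromal and epithelial markers, 5 fell when adjusted over the list alone and 2 over all genes. These were PECAM1, which myeloid cells also express (log2 -0.89 ± 0.19), and COL1A1 (log2 -2.28 ± 0.53, at 3 CPM or less in each library), and the median was -1.14 (camera adjusted p = 2.14e-06; adjusted p = 0.538 with an estimated correlation). Of 6 erythroid and megakaryocyte markers, 2 fell when adjusted over the list alone and NFE2 over all genes (log2 -1.02 ± 0.23), with a median of -0.55 (camera adjusted p = 0.0479; adjusted p = 0.538 with an estimated correlation). The 10 lymphoid markers had a median of -0.82 (camera adjusted p = 0.0209; adjusted p = 0.538 with an estimated correlation), and edgeR, DESeq2 and limma-voom each called 0, with 4 at an unadjusted p under 0.05. Medians were 0.14 for 21 mitotic genes, 0.17 for 21 DNA replication genes, 0.16 for 20 genes of ribosome biogenesis and 0.25 for 22 DNA repair genes. Camera called all 4 lists (adjusted p = 0.00798, 0.00382, 0.0303 and 0.000494; adjusted p = 0.538, 0.64, 0.657 and 0.547 with an estimated correlation). edgeR, DESeq2 and limma-voom called 0 of their members, and 0 had an unadjusted p under 0.05. The 28 interferon genes had a median of 0.15 (camera adjusted p = 0.054), with 0 called by edgeR, DESeq2 and limma-voom and 5 at an unadjusted p under 0.05. The 5 measured HOXB genes and HOX cofactors had a median of 0.26 (camera adjusted p = 0.0618), with 0 at an unadjusted p under 0.05 and 0 called by these tools.

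**Figure D5:**
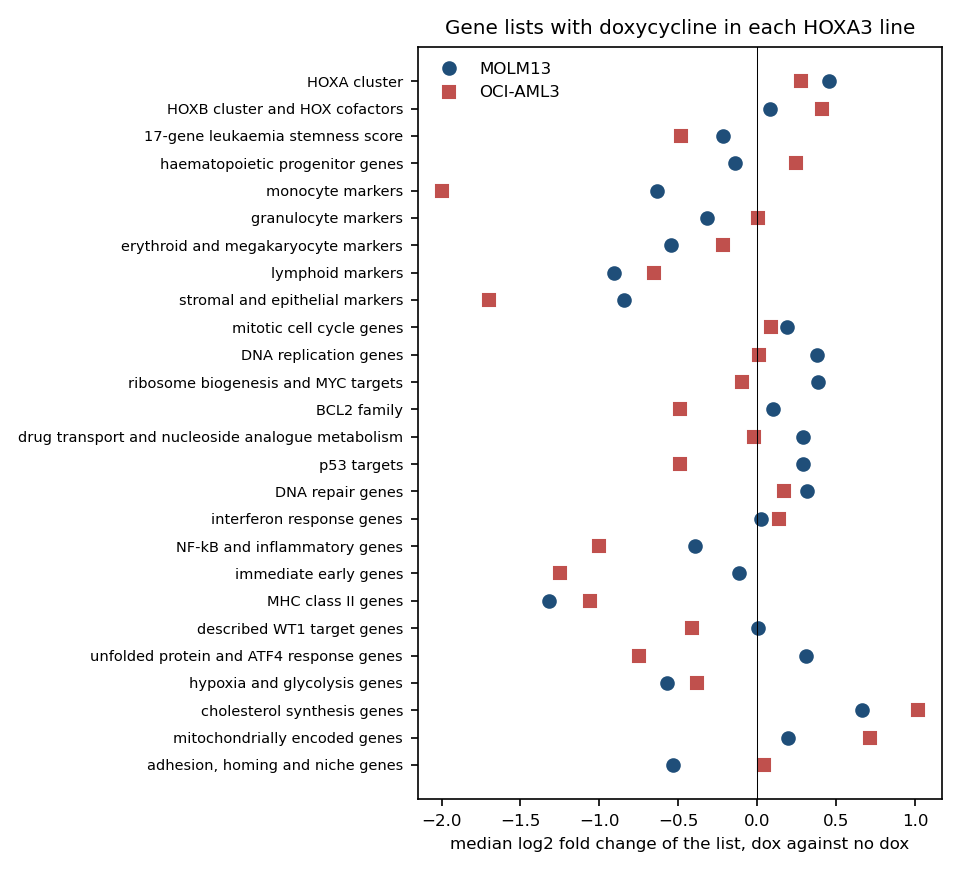
Median log2 fold change with doxycycline of each of the 26 gene lists in MOLM13 (circles) and OCI-AML3 (squares), 1 library per arm. Monocyte markers lie at -0.63 and -2, and cholesterol synthesis genes at 0.66 and 1.02.

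The genes that moved with doxycycline in both HOXA3 lines were then followed in the sWT1 groups. Of the 316 lower in both lines, the 200 with the largest smaller fold were taken, and 166 of them were tested in MOLM14. They were higher than with the empty vector in sWT1--, with a median log2 fold change of 0.96 and 129 of 166 higher, and lower in the other constructs, with medians of -0.93 in sWT1-+, -1.03 in sWT1+- and -0.59 in sWT1++. Monocyte markers, some of which the list holds, stood in the same libraries at 0.64 and 2.08 in sWT1--, -1.17 and -0.02 in sWT1-+, -1.6 and -0.27 in sWT1+-, and 0.77 and -1.26 in sWT1++, and the shift of the list was not separated from that of these markers. Camera's adjusted p was 2.66e-06, 1.77e-10, 6.98e-20 and 4.08e-15, and no call held otherwise (adjusted p = 0.393, 0.301, 0.214 and 0.232 with an estimated correlation). Of the members of this list and of the next, edgeR called 0 in any construct. The 8 genes higher in both lines, of which 6 were tested, had medians of 1.24, 1.00, 0.71 and 0.60 in the same order, with 4, 5, 3 and 4 of the 6 higher. Camera called these 6 in each construct (adjusted p = 0.0158, 0.00291, 0.00194 and 0.0101; adjusted p = 0.185 with an estimated correlation for each). With a smaller fold the 39 genes tested had medians of 0.37, 0.42, 0.72 and 0.41, and with a mean of at least 5 CPM the 4 tested had medians of 1.45, 1.19, 1.58 and 0.91. The median of the down list in sWT1-- was 0.35 without sWT1-- replicate 2 (adjusted p = 0.0878), and that in sWT1++ was -0.01 without sWT1++ replicate 2 (adjusted p = 0.82) and -1.94 without replicate 1. The up list lost its call in sWT1-- (adjusted p = 0.0755) and in sWT1++ (adjusted p = 0.0867) without empty vector replicate 2, and in sWT1+- without sWT1+- replicate 1 (median 0.29, adjusted p = 0.0663). Its median was 1.25 in sWT1+- without empty vector replicate 1, and in sWT1++ 0.26 without sWT1++ replicate 1 and 0.38 without replicate 2.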

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

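The tests of another construct, of the untransduced WT1, of the partial transcript, of a single library and of doxycycline itself were chosen after the result was seen; those of monocyte and mitochondrial levels, of depth and of other splits were not.

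A number of gene lists had medians of opposite sign in MOLM13 and OCI-AML3 with doxycycline, a difference between the lines that was not tested, since each line had 1 library per arm. As OCI-AML3 minus MOLM13, the difference in median log2 fold change was 0.39 for progenitor genes, 0.32 for granulocyte markers, -0.48 for ribosome biogenesis, -0.58 for the BCL2 family, -0.31 for drug transport and metabolism, -0.78 for p53 targets, -0.42 for described WT1 targets, -1.06 for unfolded protein and ATF4 response genes, and 0.57 for adhesion genes. By camera with the preset correlation, the effect of the second sign differed between constructs with a plus and with a minus in the first. The median log2 interaction was 2.96 for monocyte markers, -0.66 for mitotic genes, -0.52 for DNA replication genes, -0.52 for ribosome biogenesis, 0.47 for p53 targets, 3.11 for interferon genes, 0.75 for immediate early genes, 2.96 for MHC class II genes, -1.28 for mitochondrially encoded genes and 0.75 for adhesion genes. None of these interactions held with an estimated correlation (adjusted p between 0.651 and 0.694). Without sWT1-- replicate 2 the preset call ended for mitotic genes (median -0.19, adjusted p = 0.332), DNA replication genes (-0.21, 0.101), p53 targets (0.35, 0.135) and adhesion genes (0.47, 0.0666). Without sWT1-- replicate 1 the mitotic median was -1.32 and that of DNA replication genes -0.91, and without sWT1++ replicate 1 the call of immediate early genes ended (0.22, adjusted p = 0.277), as did that of MHC class II genes (0.97, adjusted p = 0.0834). The calls of mitotic, p53, immediate early and adhesion genes also ended without sWT1-+ replicate 1, the monocyte median was 1.31 without sWT1++ replicate 1, and the interferon median was 4.87 without sWT1-+ replicate 2.

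For the signs themselves, the 8 sWT1 libraries were split in other ways into 4 and 4, in an edgeR fit that took each side as a single group beside the empty vector. The real split gave 0 genes for each sign in that fit, so all 35 of the 35 splits reached that count by construction, and the comparison says nothing about chance. The highest other split gave 1452 genes and set both sWT1-- libraries, sWT1-+ replicate 2 and sWT1++ replicate 1 against the rest, and the next gave 7. Such a count points to a structure of the samples. Those 4 libraries were the lowest of the 8 on component 1, at -50, -97.9, 6.3 and -15.1, against 11 to 55.6 in the rest. Their monocyte markers were the highest, at 0.64, 2.08, -0.02 and 0.77, against -1.6 to -0.27 in the rest. The split thus ran between the replicates of sWT1-+ and of sWT1++, and its cause was not tested.

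The WT1 transcript forms of the sWT1-- libraries differed, with a KTS-plus share of 26.9% in replicate 1 and 82.1% in replicate 2. Whether replicate 2 is a library of another construct could not be decided. Its interferon genes lay 2.5 log2 above the highest of the 6 libraries of the other constructs. That level cannot identify the construct, since a response to transduction or culture of this group stays open. The share of WT1 counts in transcripts with the 51-base exon was 90.1% in replicate 1 and 59.5% in replicate 2. It was 51.8% and 53.1% in sWT1-+, 57% and 60.4% in sWT1++, and 97.6% and 97.8% in sWT1+-. These shares include partial transcripts that hold the 51-base exon in the annotation. In sWT1-+ replicate 1, WT1-207 had 3276 and WT1-208 had 4838 of 21585 WT1 counts. The shares can therefore overstate the use of that exon. WT1 of the untransduced genome would give KTS-plus shares of 4.3% and 4.4%, and the smaller gap to the measured share was 22.6 percentage points. By the 2 short full-length transcripts alone the KTS-plus shares still differed by 61.3 percentage points, so the partial KTS-plus transcript does not by itself account for the difference. These 2 transcripts differ in the 51-base exon as well as in the KTS bases. Assignment of reads from a form that fits neither of them was therefore not tested and stays open. A wrong or mixed construct in the cells of either replicate stays open and was not tested, and no biological explanation was tested.

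The higher interferon genes of sWT1-- were seen in both libraries, the lower of which lay 2.17 log2 above the highest of the other 8, which argues against 1 library carrying them. With the monocyte marker level as a covariate the median log2 fold change was 2.54, with 28 of 28 genes higher and 27 up when adjusted over the list alone. With the mitochondrial share it was 2.33, with 28 higher and 3 up when adjusted over the list alone, so neither level accounts for the whole difference of 3.93. The estimated KTS-plus share of WT1 was 26.9% and 82.1% in the sWT1-- libraries, whose interferon levels were 3.59 and 3.92. The annotation holds no short transcript for some WT1 forms, so these shares can reflect the assignment of reads. Whether interferon levels follow the KTS form therefore cannot be decided from them. No biological explanation was tested. A response to transduction or to the culture of this group stays open, because each construct was represented by 1 group of 2 libraries.

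Of the 316 genes that were lower by at least 1 log2 in both lines with doxycycline, 296 (93.7%) kept that difference after all 4 libraries were thinned to the total of the shallowest, 42605642 counts, which argues against a difference in depth behind the size of these falls. The number of calls was lower after this 1 random thinning, at 146 (140 down) against 382 (359 down). It was also lower with RLE size factors at the full depth, at 107 (102 down). With RLE factors the prior degrees of freedom of the edgeR fit were 8.5, against 17.8 in the main fit. Genes at an unadjusted p under 0.05 numbered 1390, against 1530. What lowered the number of calls was not tested. An effect of doxycycline itself and one of HOXA3 cannot be told apart, because 0 libraries had doxycycline without the HOXA3 vector.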

How the results depend on the processing

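No test here was chosen after the result was seen: all alternatives were set before the data were examined. Unless stated, the cause of a change was not tested.

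Cholesterol synthesis genes kept a positive median against the empty vector without any 1 library, from 0.81 to 1.00 in sWT1--, 0.52 to 1.00 in sWT1-+, 0.76 to 1.08 in sWT1+-, 0.32 to 1.02 in sWT1++ and 0.61 to 0.83 in the mean, and interferon genes in sWT1-- stayed between 3.48 and 4.16. Leaving out libraries gave 1613 values on the same side and in the same direction, 171 that lost a call, 10 that gained one, 30 counts that moved and 16 values that reversed. With RLE factors 217 values stayed the same and 34 lost a call, with limma-voom 139 and 1, and with a transcript length offset 165 and 7. No list named in the results held its call with an estimated correlation or by fry, including the HOXA3-responsive genes, with medians of 1.24, 1.00, 0.71 and 0.60 for the up list and 0.96, -0.93, -1.03 and -0.59 for the down list in sWT1--, sWT1-+, sWT1+- and sWT1++. Both methods let the members of a list move together, which widens the spread of their mean where they do. In the doxycycline comparison, calls were also lost where the estimated correlation was 0 (MHC class II genes) or -0.0277 (hypoxia and glycolysis genes). That comparison had 1 residual degree of freedom, so a loss there is not evidence that members moved together.

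Counts of genes changed differed between tools. In the order sWT1--, sWT1-+, sWT1+-, sWT1++, mean, first sign, second sign and interaction, edgeR gave 7, 1, 1, 1, 1, 1, 0 and 0 and DESeq2 330, 181, 38, 15, 26, 277, 361 and 966. Limma on log2(TPM + 1) gave 75 in sWT1--, 11 in sWT1-+, 2 in sWT1++, 8 for the first sign, 3 for the second and 2 for the interaction. Without a filter on low counts edgeR gave 45 in sWT1--, 95 in sWT1-+, 4 in sWT1++, 7 for the mean, 40 for the first sign, 20 for the second and 108 for the interaction. In a fit of the libraries compared alone it gave 37 in sWT1-- and 0 for the first sign. The replicate block, which pairs libraries by replicate number, gave 2 in sWT1-+, 5 in sWT1-- and 0 for the first sign. Differences between replicates correlated between groups at -0.34 to 0.32. They correlated at -0.34 to -0.28 between sWT1++ and the other constructs, and at 0.05 to 0.32 among those others. The numbers as given thus do not pair the libraries in one order, and pairing in another order was not tested. In the doxycycline comparison, edgeR called 107 genes with RLE factors, 670 without a filter and 0 without the line as a block, where the difference between the lines enters the spread.

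With a transcript length offset, the WT1 difference turned to -0.09 for the first sign, 0.48 for the interaction and -0.34 for sWT1+- against sWT1--, and that of HOXA3 to -0.16 for sWT1++ against sWT1-+. By limma on log2(TPM + 1), WT1 was -0.17, 0.47 and -0.40 in the same order, and HOXA3 -0.21 for sWT1++ against sWT1-+, 0.14 for sWT1-+ and 0.11 for the mean against the empty vector. These settings divide by the length of the transcripts counted, which differed between constructs for WT1. In single lines, the doxycycline median was 0.00 for described WT1 targets in MOLM13, and in OCI-AML3 0.00 for granulocyte markers, -0.10 for ribosome biogenesis and 0.04 for adhesion genes. Covariance between constructs moved from 0.10 to 0.03 with a different empty vector library for each construct.

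Without 1 library at a time, where a lone library is assumed to vary like the other groups, the count ranged from 0 to 18 in sWT1--, 1 to 89 in sWT1-+, 1 to 2 in sWT1++, 1 to 3 for the mean, 0 to 49 for the first sign, 0 to 19 for the second and 0 to 9 for the interaction. The count of 0 in sWT1-- was without empty vector replicate 1, and those of 89 and 49 without sWT1-+ replicate 1. Medians that changed sign ranged from -0.17 to 0.04 for described WT1 targets and -0.92 to 0.07 for mitotic genes in sWT1--, -0.06 to 0.36 for DNA replication genes in sWT1-+ and -0.05 to 0.30 in the mean, and -1.97 to 0.06 for monocyte markers in sWT1+-. In sWT1++ they ranged from -0.09 to 0.33 for ribosome biogenesis, -1.59 to 0.08 for interferon genes and -2.14 to 0.11 for inflammatory genes. HOXA3 ranged from -0.18 to 0.39 for sWT1-+ against sWT1-- and -0.09 to 0.43 for sWT1++ against sWT1-+, where WT1 ranged from -0.13 to 0.22. The HOXA3-responsive up list ranged from 0.85 to 1.40 in sWT1--, 0.29 to 1.25 in sWT1+- and 0.26 to 0.74 in sWT1++, and the down list from 0.35 to 1.35 in sWT1-- and -1.94 to -0.01 in sWT1++.

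At the depth of these libraries, thinning to the shallowest kept 296 of the 316 falls with doxycycline. In data simulated at the depth of the MOLM14 libraries, the spread was pooled over all groups and was not that of sWT1-- and the empty vector alone. For sWT1-- against the empty vector, 7 of 99 changes of 1 log2 and 62 of 99 of 2 log2 were called. At that spread, changes of 1 log2 were thus mostly not detectable with 2 libraries per group.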

Other observations

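The test in this part was chosen before its result was seen. Cholesterol synthesis genes were higher with sWT1 and with doxycycline in the HOXA3 lines, and it was tested whether the members that differed most in one differed most in the other. Over the 17 genes Pearson's r was 0.26 (permutation p = 0.313) and Spearman's rho 0.45 (permutation p = 0.0728), so the prediction was not met. Without the 2 genes farthest from the median on the sWT1 axis, r was 0.73, so the low value rests on those genes. The correlation is across genes, which are not independent replicates.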
